A study of Mus musculus with 4 samples.

How the data were processed

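The series holds droplet single-cell RNA sequencing (10x Genomics 3′ chemistry, version 2) of T cells sorted from mouse kidney allografts. Per the labels, kidneys of B6 × BALB/c F1 mice expressing ovalbumin (OVA) were placed in B6 recipients, which received effector OT-I cells on day 2, and 3 grafts per time point were taken at week 1 or week 5. An antibody to CD45 (3 µg) was injected 2 min before death so that cells inside blood vessels could be excluded, and cells bearing markers of other lineages (CD11b, CD11c, F4/80, B220, CD19, NK1.1, DX5, Ter119, CD16/32, Ly6g) were left out of the sort. OT-I cells and polyclonal T cells of each graft were sorted separately, marked with an oligonucleotide-labelled antibody (hash tag) per graft, pooled by sort, and loaded at 7000 cells per sample. Each sort is therefore 1 library, and a graft is a hash tag within it.

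The authors' processing is known only in part. Per the submitters' processing notes, the mouse build mm10, STAR and Partek 9.0.20.0110 were used, with no role stated for either tool. The filters on cells and genes, the gene annotation, the method of hash tag assignment, the handling of unique molecular identifiers and the use of strand are not given in the sources used here. The deposited tables hold 1 line per cell with its hash tag, its time label (Week 1 or Week 5), a column headed Total count and 1 column per gene. The gene values were deposited on a log2 scale: each equals log2(x + 1), where x is a whole gene count times 1000000 divided by the cell's Total count. The deposited Total count column holds whole-number counts per cell whose meaning is not stated. It is not the sum of the cell's gene counts, which was larger by a median factor of 21.0 in the OT-I table and 17.2 in the polyclonal table. The deposited log2 values are thus not scaled to the RNA depth of a cell. The hash tag entries hold the lists of 6 tags per sort and no counts per cell.

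Gene counts were recovered by undoing the log2 transform. For OT-I cells 100% of 6472070 nonzero values, and for polyclonal cells 100% of 14101122, lay within 0.1 of a whole number. A count here means such a recovered value. It is called a count and not a molecule because deduplication is not stated, and confidence intervals cover counting error only. Cells with at least 500 counts, 200 genes and at most 10% mitochondrial counts were kept. This kept 6418 of 6580 OT-I cells and all 11700 polyclonal cells. The tables hold 12318 and 15293 genes, of which 12294 are shared and 24 and 2999 occur in 1 table only, so that comparisons between the sorts rest on the shared genes. Klrg1 and P2rx7 of the fixed lists, for example, are not in the OT-I table. Polyclonal cells with a count of Cd8a or Cd8b1 and none of Cd4 were gated as CD8 cells, and those with a count of Cd4 and none of Cd8a or Cd8b1 as CD4 cells. No kept OT-I cell had a count of Cd4, so the CD8 gate of OT-I cells rests on Cd8a and Cd8b1 alone. In polyclonal cells the same gate also left out 1145 cells with counts of both gates' genes, so the gates are not alike between the sorts. These genes are no finding in any comparison of the gates. Scrublet marked 0 doublets in either library, so this caller was taken not to have worked, and no result without doublets was computed.

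Counts were summed per graft, over all kept OT-I cells for changes between time labels, over CD8-gated OT-I cells for their contrast with polyclonal CD8 cells over all grafts, and per gate in polyclonal cells. Grafts served as replicates (n = 3 per time point). The edgeR quasi-likelihood test, a count model, had been planned for the time comparisons and their difference between the sorts. It was replaced once the deposited values were seen to be log2 values, although counts could be recovered from them. The main test was therefore limma-trend (limma 3.58.1, R 4.3.3) on log2(CPM + 1) of the sums, with TMM scaling and the expression filter of edgeR 4.0.16 and robust empirical Bayes moderation. CPM is the count per 1000000 counts of the sum, scaled in each test by TMM over the sums of that fit. The CPM of a gene in a graft therefore differs slightly between fits. Fold changes are log2 differences on the log2(CPM + 1) scale, which understates changes of low genes. P-values were adjusted by Benjamini-Hochberg, with calls at an adjusted p under 0.05. The edgeR quasi-likelihood test and DESeq2 1.42.0 on the recovered counts were alternatives. The difference of the time change between OT-I and polyclonal CD8 cells was an interaction term over 12 sums. For OT-I against polyclonal CD8 cells and CD4 against CD8 cells, counts were pooled over grafts and compared as log2 ratios of CPM with a pseudocount of 1 CPM, among genes with at least 100 CPM on 1 side. Conditional binomial intervals (95%) belong to the ratio without pseudocount. A limma test on graft sums was added for both, with a term for the graft in the CD4 against CD8 fit.

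A total of 18 gene lists and marker lists of other cell types were fixed before the data were examined. Lists were tested with camera at a preset correlation between genes of 0.01 and again with an estimated correlation, and the median of a ratio list was placed among 10000 random lists matched on expression. The genes named were also set by a rule. For the tests these are the 10 largest rises and 10 largest falls among called genes with at least 50 CPM on average in 1 group and groups that do not overlap, plus called members of both resident memory lists. Grafts of 2 groups of 3 fail to overlap by chance for 10% of genes. For the ratios these are the 10 largest in each direction among genes at 100 CPM and in at least 10% of cells on that side, plus members of the resident memory and inhibitory receptor lists at 50 CPM with a log2 ratio of at least 1 in size. Antigen receptor and immunoglobulin segments, mitochondrial and ribosomal genes and unnamed gene models were left out. Other list members stand as examples. Coordinates are from the GENCODE vM21 annotation of mm10.

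Cells of each library were normalised with scanpy 1.11.5, which also ranked genes for the choice of 2000 variable ones. They were clustered by the Leiden method of igraph, by modularity, on a graph weighted by shared neighbours (20 principal components, 15 neighbours, resolution 0.8, seed 20240). A cluster was named after a cell type when at least 3 of that type's fixed markers stood among its 30 leading genes. Shares of cells with a count were computed at full depth and after thinning each cell to 1200 counts, the 20th percentile of the shallower library rounded down to a multiple of 100. Thinning left out 631, 189 and 216 OT-I cells labelled week 1 and 31, 39 and 23 labelled week 5. The polyclonal cells left out numbered 416, 386 and 395 at week 1 and 62, 182 and 179 at week 5. The share of a single group has an exact binomial interval, and shares per graft were compared by exact 2-sided permutation tests, whose smallest possible p with 3 against 3 grafts is 0.1. Sequence families of ribosomal genes were built with blastn 2.17.0 (at least 80% identity over at least 200 bases).

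Each fitting step was tested on simulated counts with known changes. Changes were set only in genes above a floor of expression, with 67 genes at 2-fold in each fit. The shares recovered therefore do not hold for lowly expressed genes. Of genes changed 2-fold, 86.6% were recovered in the OT-I time comparison (9721 genes), 100% in the polyclonal CD8 one (10523 genes), 25.4% in the CD4 one (4569 genes) and 65.7% in the interaction (10851 genes). False calls made up 7.43%, 3.33%, 0% and 4.58% of calls. In the test between the sorts (10813 genes) 100% were recovered with 5.39% false calls, and in the CD4 against CD8 test (9292 genes) 61.2% with 0.87%. Simulated counts were drawn independently for each sum from a common profile, with rises and falls in like number and no graft effect. The shares of false calls therefore do not hold where sums share grafts or where the split of calls depends on the scaling. Alternatives were other scalings, other tests, no filter on low counts, pseudocounts of 5 and 10 CPM, other cell filters, thinned cells, means over cells, clusters in place of gates, cells without proliferation genes, gene sets left out and each graft left out in turn.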

Results

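T cells that had entered OVA-expressing mouse kidney allografts were profiled by single-cell RNA sequencing at week 1 and week 5 after transplantation. OT-I cells are CD8 T cells of a transgenic mouse line that carry 1 T cell receptor, specific for a peptide of OVA, and the polyclonal cells are the recipients' remaining graft T cells. Each sort formed 1 pooled library in which a hash tag marked the graft, with 3 grafts at each time point. The OT-I table held 6418 cells after filtering, with 1395, 707 and 1042 cells in the week 1 grafts and 1133, 1325 and 816 in the week 5 grafts. The polyclonal table held 11700 cells, with 2886, 1700 and 1728 cells at week 1 and 1067, 2235 and 2084 at week 5. Total counts ran from 1155657 to 3807599 per graft in OT-I cells and from 3026489 to 7257426 in polyclonal cells. OT-I cells labelled week 1 were shallower (median 1238, 1427 and 1597.5 counts per cell in the 3 grafts) than those labelled week 5 (2344, 2222 and 2578.5), and the same held for polyclonal cells, with medians of 2200.5, 1838.5 and 1743.5 at week 1 and 2479, 2265 and 2351 at week 5. The CD8 gate held 1533127 to 5780279 counts per polyclonal graft. The CD4 gate held only 86838 to 920079, from 56 to 319 cells per graft, which limits what could be called in CD4 cells. The cells are described by the time labels of the table, as cells labelled week 1 or week 5.

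Receptor segment counts were examined first, because the labels give OT-I cells a single receptor. Trav14, as the near-identical copies Trav14n-1 and Trav14d-1, took 252 of 298 Trav counts in OT-I cells (84.6%, exact interval 79.95% to 88.47%), and Trav22 took the other 46. Trbv12-1 took all 192 Trbv counts and was the 1 Trbv segment in that table. In polyclonal cells 54 Trav segments had counts, the most frequent being Trav16n with 9.77% of 2180 counts. Trbv segments gave only 211 counts there, from the 5 segments in that table, and Trbv12-2 took 154 of them (72.99%, 66.46% to 78.85%). Reads of near-identical segments can be split between copies by the counting, so single members of a V family are uncertain.

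By the count of fixed markers, clustering assigned 64.4% of the polyclonal cells, with 1 cluster of 20.1% among them that is left without a name here. Naive or central memory T-like cells made up 20.2% of the 11700 cells, regulatory T-like cells 12.6% and interferon-responding T-like cells 1.496%. That cluster reached the count for resident memory T cells, with Itga1, Cxcr6 and Itgae, but only at the main clustering setting. Its 10 leading genes held none of these and held the gamma delta T marker Tcrg-C2. Of the cells in this cluster 93.73% were CD8-gated, and CD8 T was the type with the next most markers. A gamma delta identity is therefore not read from Tcrg-C2. NK and ILC1-like cells made up 6.09%, proliferating cells 1.58%, macrophage and monocyte-like cells 1.61% and kidney tubule-like cells 0.846%. The sort excluded cells stained for NK1.1, CD11b or F4/80 and cells in blood vessels. Of the NK and ILC1-like, macrophage and monocyte-like and kidney tubule-like clusters, 45.16%, 72.34% and 73.74% of cells were CD8-gated. These names therefore do not show that such cells passed the sort. Of the OT-I cells 5.19% were named: 2.32% as naive or central memory T-like, 1.90% as proliferating and 0.966% as interferon-responding.

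The makeup of the polyclonal cells by gate differed between the time labels. CD8-gated cells made up 76.6% ± 2.91 of polyclonal cells labelled week 1 (SD, n = 3 grafts) and 49.2% ± 3.25 of those labelled week 5, with no overlap between grafts. Cells with counts of neither gate's genes made up 10.38% ± 3.00 and 27.05% ± 2.66, the largest gain, and CD4-gated cells 3.16% ± 0.249 and 14.0% ± 2.32. Cells with a count of Foxp3, the defining transcription factor of regulatory T cells, made up 5.39% ± 1.34 and 17.2% ± 3.81. Cells with counts of both gates' genes made up 9.89% ± 0.363 and 9.79% ± 0.982. The exact permutation test gave p = 0.1 for the first 4 shares, the smallest value that 3 against 3 grafts allow, and p = 1.0 for the last.

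**Figure D1:**
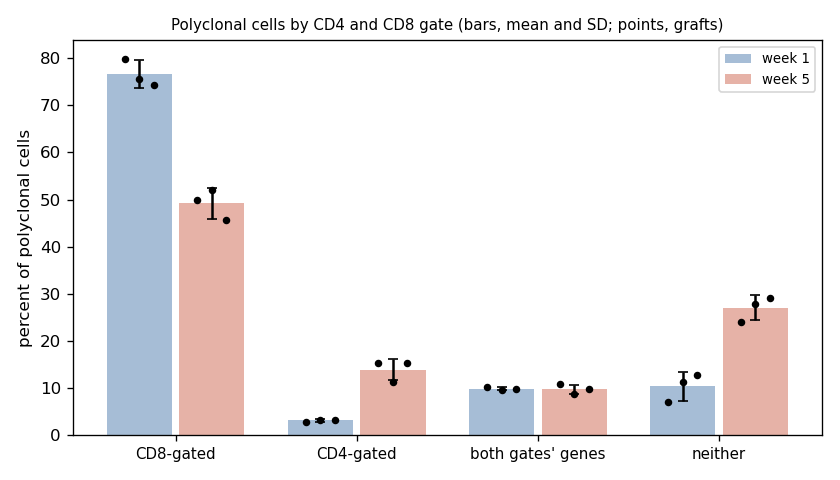
Percent of polyclonal cells in each gate per graft, with bars for the mean of 3 grafts, error bars for the SD and points for single grafts. The CD8-gated share lies between 74.25% and 79.83% in grafts labelled week 1 and between 45.68% and 52.08% in those labelled week 5.

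In OT-I cells, the recirculation genes Slamf6 and Klf2 and the cytokine gene Ifng were higher in cells labelled week 5, and the residency integrin genes Itgae and Itga1 were lower. Ly6c2, a surface marker of circulating effector and memory CD8 cells, rose from 26.1 ± 1.53 to 109 ± 4.24 CPM (SD, n = 3 grafts; log2 change 2.02 ± 0.13 SE, adjusted p = 8.9e-09). Slamf6, a receptor kept by less differentiated CD8 cells, rose from 2.31 ± 0.964 to 23.5 ± 4.48 CPM (2.91 ± 0.29), and Klf2, a transcription factor that maintains expression of S1pr1 and Sell, rose from 14.6 ± 2.34 to 48.7 ± 11.2 CPM (1.66 ± 0.20). Ifng, the gene of interferon gamma, rose from 112 ± 28.6 to 300.0 ± 7.85 CPM (1.44 ± 0.13, adjusted p = 8.07e-06). Itgae, which encodes CD103, the integrin that binds E-cadherin, fell from 21.9 ± 5.18 to 5.76 ± 1.88 CPM (−1.77 ± 0.27, adjusted p = 0.00019). Itga1, which encodes the collagen-binding CD49a, fell from 156 ± 29.0 to 92.7 ± 16.5 CPM (−0.75 ± 0.15). The largest other rises were Il18r1 (2.19 ± 0.41), the galectin gene Lgals1 (1.77 ± 0.20, from 541 to 1813 CPM), Kdm6b, Pim2, Tpm4, Klrk1, Glipr2 and Emp3, between 1.35 and 1.61 for the last 6. The largest falls were Zfp512 (−1.72 ± 0.17), the interleukin 7 receptor gene Il7r (−1.57 ± 0.28), Ssbp2, Tnfsf8, Txnip, Camk2n1, Ccnd2, Insig1, Spry2 and Zbtb20, from −1.54 for Ssbp2 to −1.03 for Spry2, with Zbtb20 at −0.9999. The calls of Il7r, Il18r1, Klrk1, Spry2, Pim2, Tnfsf8 and Cdh1 were each lost when any of several single grafts was left out, and those of Lgals1 and Tpm4 without replicate 3 of week 5.

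The limma test called 603 genes higher and 450 lower in OT-I cells labelled week 5, of 9721 tested. The TMM-scaled changes had a median of −0.02 over all genes. Scaled by total counts alone the median was −0.12 and the calls split 384 higher to 775 lower, so the direction of small changes depends on the scaling. The count fell to 641 without replicate 1 of week 1, to 669 without its replicate 3 and to 603 without replicate 2 of week 5. Ly6c2 lies at chromosome 15:75108158-75111970 on the minus strand (mm10), among near-identical Ly6 genes that can share reads. Itga1 lies at 13:114953096-115101964 (minus), Itgae at 11:73090583-73147446 (plus), Slamf6 at 1:171917515-171953170 (plus), Klf2 at 8:72319033-72321656 (plus) and Ifng at 10:118441046-118445892 (plus), all protein-coding. Strand use in the counting is not stated, so reads of antisense partners cannot be separated.

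Of the lists in OT-I cells, AP-1 and antigen receptor signalling had 9 members higher and 0 lower of 18 tested (13 and 0 adjusted over the list alone). Among them were Nr4a2 (0.81 ± 0.10), Nr4a1 (1.75 ± 0.39), Junb (0.63 ± 0.10) and Irf4 (1.60 ± 0.39), genes induced by receptor signalling. Its median was 0.62 (camera adjusted p = 4.42e-07; adjusted p = 0.146 with an estimated correlation). The dissociation stress list, which shares AP-1 genes with it, had 4 higher of 16 (camera adjusted p = 0.00248; adjusted p = 0.286 with an estimated correlation). The recirculation list had 5 higher and 0 lower of 12 (6 and 1 over the list alone), including Cx3cr1 (2.24 ± 0.42), with a median of 0.45 (0.000249; adjusted p = 0.393 with an estimated correlation). The resident memory list had 3 higher and 5 lower of 25 (5 and 9 over the list alone), a median of −0.05 and an adjusted p of 0.289. Its higher members were Nr4a1, Nr4a2 and Sik1, which are signalling genes, and its lower members were Itgae, Itga1, Cdh1, Inpp4b and Qpct. Cxcr6, a chemokine receptor that marks tissue CD8 cells, changed by −0.31 ± 0.11, with an adjusted p of 0.0672.

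The inhibitory receptor list in OT-I cells had 5 higher and 0 lower of 13 (7 and 0 over the list alone; camera adjusted p = 0.0014; adjusted p = 0.286 with an estimated correlation). Those called were Havcr2 (1.49 ± 0.25), Ctla4 (1.17 ± 0.17), Cd200 (1.19 ± 0.21), Rgs16 and Lag3 (0.55 ± 0.09), while Pdcd1, which encodes PD-1, changed by −0.17 ± 0.10 and was not called. Proliferation genes had 9 higher and 2 lower of 18 (12 and 2 over the list alone) with a median of 0.99 (3.65e-06; adjusted p = 0.362 with an estimated correlation), the higher ones including Ccnb2 (2.31 ± 0.47) and Top2a (1.02 ± 0.20) and the lower ones being the tubulin genes Tuba1b and Tubb5. This list's adjusted p was 0.117 without cells that held a count of Mki67, Top2a, Birc5, Cdk1 or Ccnb2, a choice that lowers the list by construction. The interferon-stimulated list had 3 higher of 16 (Isg15, Stat1 and Zbp1; adjusted p = 0.0014, and 0.169 in cells thinned to 1 depth), cytokines and chemokines 4 higher and 1 lower of 10 (adjusted p = 0.0342), with Ccl5 at 1.12 ± 0.16, and circulating effector genes 2 higher of 6 (adjusted p = 0.0211). With an estimated correlation the adjusted p of these 3 lists was 0.479, 0.479 and 0.425. Without replicate 3 of week 5 the adjusted p was 0.176 for cytokines and 0.0816 for circulating effector genes. The camera adjusted p was above 0.05 for naive and central memory (1 higher and 1 lower of 5, with a median of −0.34 and a mean of 0.08), cytotoxicity (0 and 2 of 12), homing receptors (1 and 1 of 12), glycolysis (2 and 0 of 14), lipid uptake (1 and 1 of 11), common gamma chain receptors and survival (4 and 5 of 18), TGF-beta pathway (0 and 1 of 10), NK-type receptors (2 and 2 of 11) and subset transcription factors (1 and 1 of 15). Markers of other cell types moved too. Regulatory T markers had 4 higher and 1 lower of 6, with Izumo1r at 2.22 ± 0.32 and Tnfrsf4 at 1.76 ± 0.46 (adjusted p = 0.0184; 0.362 with an estimated correlation; 0.0823 without cells that held a count of the 5 proliferation genes). Macrophage markers had 2 higher of 5, Ccr2 and Ctss, both also expressed by T cells (adjusted p = 0.0287; 0.479 with an estimated correlation; 0.173 without replicate 3 of week 1), and ILC2 markers had 1 lower of 3, Calca (0.0213; 0.362 with an estimated correlation). Markers of erythroid, kidney tubule, dendritic, B, plasma and NK cells gave adjusted p-values of 0.0973, 0.458, 0.555, 0.295, 0.0973 and 0.167.

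In polyclonal CD8 cells, the resident memory genes Itga1, Itgae and Cxcr6 were lower under the week 5 label, and genes of naive and recirculating cells such as Tcf7, Sell and Slamf6 were higher. Itga1 fell from 111 ± 14.1 to 35.9 ± 3.61 CPM (SD, n = 3 grafts; log2 change −1.60 ± 0.12 SE, adjusted p = 9.58e-08), and Itgae from 103 ± 22.8 to 56.0 ± 3.69 CPM (−0.85 ± 0.14). Cxcr6 fell from 1183 ± 146 to 449.8 ± 144 CPM (−1.43 ± 0.26, adjusted p = 0.0278), a call lost when any 1 of 5 single grafts was left out. Tcf7, a transcription factor of naive and stem-like T cells, rose from 45.7 ± 1.98 to 150.2 ± 29.3 CPM (1.68 ± 0.12, adjusted p = 9.4e-08). Sell, the lymph node homing receptor CD62L, rose from 22.9 ± 6.14 to 156 ± 71.0 CPM (2.65 ± 0.41, adjusted p = 0.0151), a call also lost without any 1 of 3 grafts. Slamf6 rose by 1.83 ± 0.11, Lef1 by 1.67 ± 0.22, Satb1 by 2.00 ± 0.18, Ly6c2 by 2.10 ± 0.25 and Dapl1 by 2.87 ± 0.36. The remaining largest rises were Zbtb32, Adk, Cd200 and Izumo1r, between 1.70 and 2.12. Izumo1r is a regulatory T marker, and the CD8 gate is not pure. Of the regulatory T-like cluster 21.39% of cells were CD8-gated and 25.41% CD4-gated. Among CD8-gated cells that cluster took a larger share at week 5 than at week 1. Rises of regulatory T markers are thus not shown to lie in CD8 T cells. The remaining largest falls were Adgrg1 (−2.18 ± 0.19), the death ligand gene Fasl (−1.59 ± 0.13, from 157 to 52.3 CPM), Cd244a, Cd200r4, Camk2n1, Chn2, Padi2 and Metrnl, between −1.73 and −1.34 for the last 6.

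The limma test called 1217 genes higher and 898 lower in polyclonal CD8 cells, of 10523 tested, with a median of −0.03 over all genes. Each sum takes in all CD8-gated cells of a graft, or all kept cells in OT-I cells, so a change in the mix of cell states and a change within cells are not separated. The cells compared lie largely in different clusters, which were built without leaving out the called genes. Most OT-I cells labelled week 1 lie in clusters 1 and 3 and most of those labelled week 5 in clusters 2 and 4. Most CD8-gated polyclonal cells labelled week 1 lie in clusters 1 and 2, and most of those labelled week 5 in clusters 6, 1 and 9. Without TMM the median was −0.14 and the split was 774 to 1607. Without replicate 1 of week 1 the count was 1274, and without its replicate 3 it was 1313. Cxcr6 lies at chromosome 9:123806475-123811760 (plus), Tcf7 at 11:52252371-52283014 (minus), Sell at 1:164061982-164084181 (plus) and Satb1 at 17:51736187-51833290 (minus), all protein-coding.

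The resident memory list in polyclonal CD8 cells had 13 members lower and 2 higher of 29 (16 and 5 adjusted over the list alone) and a median of −0.39 (camera adjusted p = 0.000117; adjusted p = 0.338 with an estimated correlation). Besides Itga1, Itgae and Cxcr6 the lower members included Cdh1 (−1.47 ± 0.19), Qpct (−1.47 ± 0.22), Nr4a2 (−0.90 ± 0.19), Cd101, Dusp6, Litaf, Rgs2, Runx3, Inpp4b and Skil, and the higher ones were Rgs10 (0.96 ± 0.08) and Nr4a1 (0.63 ± 0.15). The recirculation list had 11 higher and 0 lower of 20 (12 and 0 over the list alone) and a median of 0.92 (7.25e-06; adjusted p = 0.428 with an estimated correlation), with S1pr1, the receptor for egress from tissue, at 0.92 ± 0.23, Klf3 at 1.05 ± 0.21, and Cmah, Itgb7, S1pr4 and Sidt1 among its members. The calls of Nr4a2, S1pr1, S1pr4 and Skil were lost without any of several single grafts, and those of Inpp4b and Dapl1 without replicate 1 of week 1. Naive and central memory genes had 7 higher and 0 lower of 10 (8 and 0 over the list alone), a median of 1.66 and an adjusted p of 3.91e-06 (adjusted p = 0.338 with an estimated correlation). Glycolysis genes had 8 higher and 0 lower of 15 (8 and 0 over the list alone), led by Slc16a3 (1.05 ± 0.24), Tpi1 (0.78 ± 0.11) and Ldha (0.76 ± 0.06), which makes lactate (adjusted p = 8.48e-05; adjusted p = 0.338 with an estimated correlation). Proliferation genes had 9 higher and 0 lower of 19 (11 and 0 over the list alone), among them Stmn1 (1.08 ± 0.13) and Birc5 (1.83 ± 0.43), with an adjusted p of 1.95e-05 (adjusted p = 0.428 with an estimated correlation; adjusted p = 0.387 without cells that held a count of those same 5 genes).

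The other lists in polyclonal CD8 cells had camera adjusted p-values above 0.05, though many had members called in both directions. Of inhibitory receptors 5 were higher, among them Btla (1.26 ± 0.22), and 4 lower of 15, among them Pdcd1 (−0.68 ± 0.09) and Tox (−0.36 ± 0.10). Of subset transcription factors 6 were higher, among them Foxp3 (1.31 ± 0.23), and 5 lower of 20, among them Id2 (−0.99 ± 0.06). AP-1 genes had 5 higher, including Egr2 and Egr3, and 2 lower of 20, with a median of −0.01 and a mean of 0.12, and the stress list 1 and 2 of 18. The counts were 3 higher and 3 lower of 13 for cytotoxicity, 1 and 2 of 14 for cytokines, 2 and 4 of 17 for homing receptors, 4 and 0 of 19 for interferon-stimulated genes, 0 and 1 of 11 for lipid uptake, 5 and 4 of 19 for common gamma chain receptors and survival, 1 and 4 of 12 for TGF-beta, 1 and 4 of 14 for NK-type receptors and 1 and 1 of 7 for circulating effector genes. Markers of other T cells moved with these groups. Regulatory T markers had 5 higher of 8 (adjusted p = 3.78e-05; adjusted p = 0.428 with an estimated correlation), and their median of 0.82 was 0.01 (adjusted p = 0.714) when clusters replaced the gates. Gamma delta T markers had 4 lower, Tcrg-C1 (−1.31 ± 0.16), Tcrg-C2, Tcrg-C4 and Trgv2, and 1 higher, Trdc, of 5 (adjusted p = 0.0131; adjusted p = 0.455 with an estimated correlation). Macrophage, kidney tubule, B, erythroid, dendritic, NK, plasma and ILC2 markers gave adjusted p-values from 0.136 to 0.961.

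**Figure D2:**
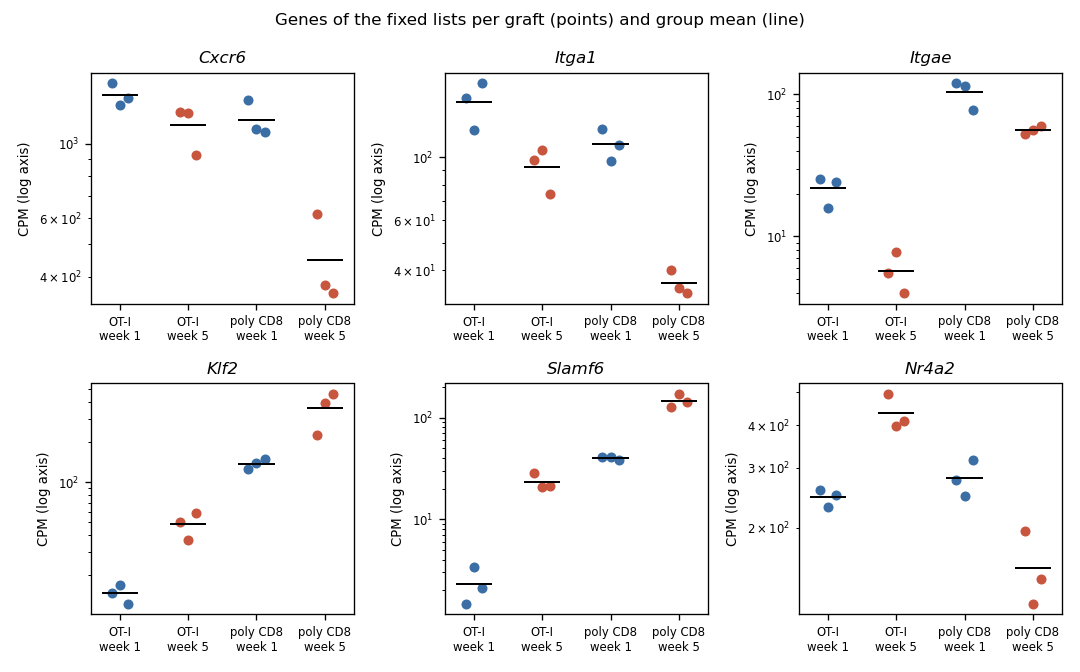
CPM of 6 list genes per graft on a log axis, in OT-I cells and polyclonal CD8 cells, with blue points for grafts labelled week 1, red points for week 5 and a line for the mean of 3 grafts. Itga1 is lower under the week 5 label in both sorts, and Nr4a2 is higher in OT-I cells (246 to 434 CPM) and lower in polyclonal CD8 cells (280.2 to 152 CPM).

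In polyclonal CD4 cells, Gzmb, Il10 and 3 of 8 regulatory T markers were higher under the week 5 label, and the cytokine genes Xcl1, Ccl3, Ifng and Tnf were lower. CD4-gated cells labelled week 5 lie far more often in the regulatory T-like cluster than those labelled week 1, and Il10 is a leading gene of that cluster. A change in the mix of CD4 cells and a change within them are not separated. Gzmb, the granule protease granzyme B, rose from 49.5 ± 48.8 to 526 ± 241 CPM (SD, n = 3 grafts; log2 change 3.77 ± 0.66 SE, adjusted p = 0.046). Il10, an anti-inflammatory cytokine gene, rose from 51.1 ± 8.46 to 256 ± 98.5 CPM (2.24 ± 0.30, adjusted p = 0.00743), and Matk rose by 2.59 ± 0.33. The chemokine genes Xcl1 (−1.53 ± 0.25, from 417 to 151 CPM) and Ccl3 (−1.17 ± 0.24) fell, as did Ifng (−0.98 ± 0.17), Tnf (−1.72 ± 0.36), Cxcr6 (−1.04 ± 0.16) and the enkephalin precursor gene Penk (−2.99 ± 0.62). The remaining largest rises were Snx9, Ass1, Arl5a, Ccr2, Fam169b, Timp2 and Glrx, between 1.51 and 2.51, and the remaining falls Dct, Rbpj, Il18r1, Nrp1 and Cxcr4, between −2.52 and −1.27. The limma test called 29 genes higher and 16 lower of 4569. The split was 32 to 1 without the filter on low counts and 19 to 1 without replicate 3 of week 1, so the falls depend on both. Most of these calls rest on few cells: without 1 graft the count was 11 (replicate 1 of either week), 18 or 20 (replicates 2 and 3 of week 1), 37 or 14 (replicates 2 and 3 of week 5). Of the 10 largest rises and 10 largest falls, each except Glrx and Matk lost its call without at least 1 of the grafts.

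Regulatory T markers in CD4 cells had 3 members higher and 0 lower of 8 (7 and 0 adjusted over the list alone), namely Izumo1r (1.46 ± 0.17), Ctla4 (1.25 ± 0.24) and Capg, with a median of 0.94 (camera adjusted p = 5.34e-09; adjusted p = 0.468 with an estimated correlation). Cytokines and chemokines had 1 higher and 4 lower of 10 (2 and 5 over the list alone) and a median of −0.98, and the resident memory list had 0 higher and 2 lower of 18, Cxcr6 and Xcl1 (1 and 5 over the list alone), both with an adjusted p of 0.0232 (0.468 and 0.545 with an estimated correlation). The latter's adjusted p was 0.734 without replicate 2 of week 1, and that of cytokines 0.165 without replicate 2 of week 5 and 0.375 in thinned cells. Interferon-stimulated genes had 1 higher of 14, Ifi27l2a, and an adjusted p of 0.0167 (0.468 with an estimated correlation). That call was lost without replicate 2 of week 1 (0.0564) or of week 5 (0.0769), in thinned cells (0.28) and with clusters in place of gates (0.235). For the other lists the adjusted p ran from 0.0574 (glycolysis) to 0.906 (cytotoxicity).

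The change between time labels was compared between OT-I and polyclonal CD8 cells by an interaction term, in which a positive value means a larger rise, or a smaller fall, in OT-I cells. Nr4a2, an orphan nuclear receptor induced by receptor signalling, went from 261 ± 14.8 to 464 ± 55.2 CPM in OT-I cells and from 261 ± 32.1 to 145 ± 37.2 CPM in polyclonal CD8 cells (difference 1.69 ± 0.21 SE, adjusted p = 0.00122, n = 3 grafts per group). Klf6 went from 234 to 480.2 CPM in OT-I cells and from 488 to 378 in polyclonal ones (1.40 ± 0.12, adjusted p = 3.02e-07). Igfbp7, a secreted binding protein, went from 34.1 to 83.5 and from 31.5 to 16.7 CPM (2.19 ± 0.27), and the inhibitory receptor gene Havcr2 differed by 1.67 ± 0.34. Satb1, a chromatin organiser of thymic and naive T cells, went from 20.03 to 87.95 CPM in polyclonal cells and stayed at 12.8 and 11.1 CPM in OT-I cells (−2.36 ± 0.48). Itga1 fell in both sorts, and less in OT-I cells (0.83 ± 0.20, adjusted p = 0.0399). The calls of Satb1 and Itga1 were lost when any of several single grafts was left out. The limma test called 73 genes higher and 90 lower of 10851. The count was 97, 94 and 82 without polyclonal replicates 1, 2 and 3 of week 1, and 82 without polyclonal replicate 2 of week 5.

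By list, AP-1 genes had 4 higher and 0 lower of 18 in the interaction (7 and 0 adjusted over the list alone), namely Nr4a2, Junb (0.71 ± 0.12), Jund (0.57 ± 0.10) and Tnfaip3 (0.79 ± 0.18), and a median of 0.64 (camera adjusted p = 9.3e-09; adjusted p = 0.0558 with an estimated correlation). The stress list, which shares Junb and Jund, had 2 higher of 18 (0.00191; adjusted p = 0.0877 with an estimated correlation). Inhibitory receptors had 3 higher of 15, Havcr2, Cd38 and Cd244a (8 and 0 over the list alone; 3.35e-06), the resident memory list 4 higher and 0 lower of 27, Itga1, Nr4a2, Rgs2 and Sik1 (8 and 3 over the list alone; 0.0011), and naive and central memory genes 2 lower of 9, Satb1 and Bach2 (0 and 4 over the list alone; 0.000323), each with an adjusted p = 0.0558 with an estimated correlation. Glycolysis had 1 lower of 15, Ldha (−0.55 ± 0.11; 0.013), and circulating effector genes 1 higher of 6, Cx3cr1 (0.03), both with an adjusted p = 0.258 with an estimated correlation. Cytotoxicity and cytokines each had 1 higher of 12, Fasl and Ccl5 (0.0351; 0.494 and 0.464 with an estimated correlation), and both list calls were lost without the filter on low counts (0.0689 and 0.0574) and without OT-I replicate 3 of week 5 (0.422 and 0.34) or any of several other grafts. The call of circulating effector genes was lost without any of 4 grafts. Erythroid markers moved in the same direction with 0 of 4 called (0.03; adjusted p = 0.455 with an estimated correlation), as did kidney tubule markers with 0 of 7 called (0.0497; adjusted p = 0.494 with an estimated correlation), and both calls were lost without some of the grafts. The recirculation list had 2 higher and 1 lower of 20 (0.98).

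**Figure D3:**
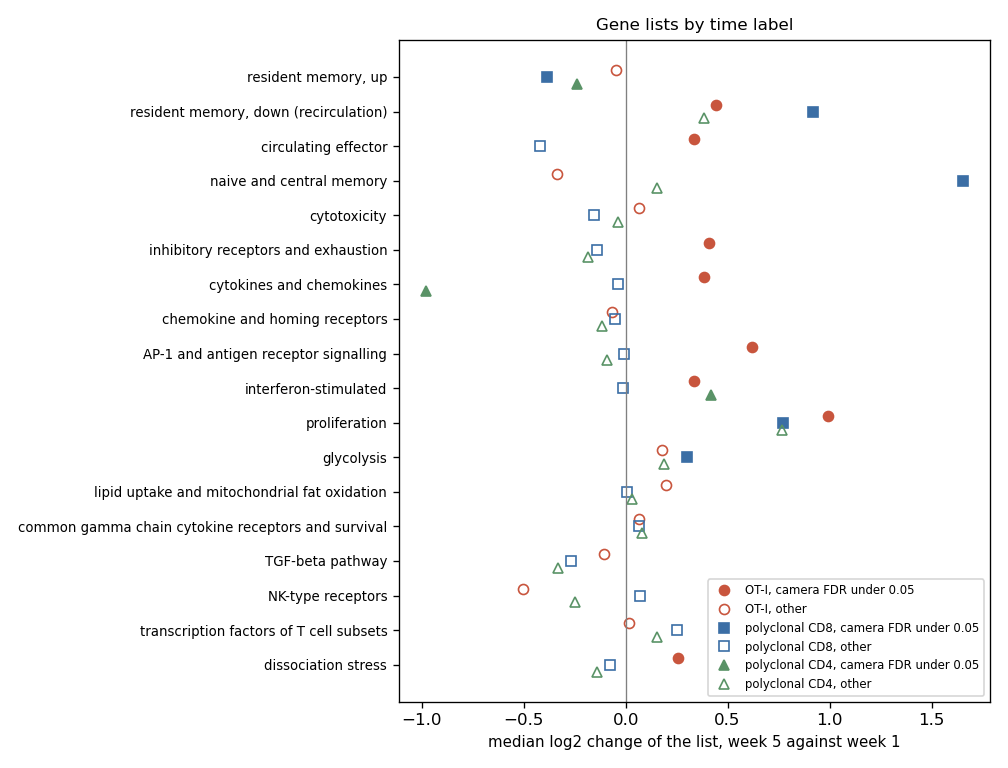
Median log2 change between week 5 and week 1 labels for the 18 lists, with circles for OT-I cells, squares for polyclonal CD8 cells and triangles for polyclonal CD4 cells, filled where the camera adjusted p was under 0.05. The AP-1 list lies at 0.62 in OT-I cells and −0.01 in polyclonal CD8 cells, and the naive and central memory list at −0.34 and 1.66. In OT-I cells the latter list rests on 5 genes with a mean of 0.075 (camera adjusted p = 0.908).

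OT-I cells were next compared with polyclonal CD8 cells over all grafts. The contrast is also one of library against library, so sort and library cannot be told apart, and the pooled ratios have no replicate check and weigh the weeks unequally in the 2 sorts. Fcer1g, an adaptor of innate receptors, stood at 1336 CPM in OT-I cells and 132 in polyclonal CD8 cells (log2 ratio 3.33; without pseudocount 3.34, counting interval 3.28 to 3.40). Klrc2, which encodes the activating NK receptor NKG2C and has the near-identical relative Klrc1, stood at 839 and 342 CPM (1.29; 1.25 to 1.34). The aspartic protease gene Ctse had 16 counts against 2355 (1.07 and 121 CPM; −5.88, without pseudocount −6.81 with −7.62 to −6.11). Cxcr4 (−5.19), Tnfrsf4 (−5.07), Itgb7 (−4.55), Izumo1r (−4.09), Klf2 (−2.80), Kcnn4, Ikzf2, Emb and Ly6c2 (−2.18) were also lower in OT-I cells. Tnfrsf4, Izumo1r and Ikzf2 are regulatory T markers, and the polyclonal CD8 gate also held cells of the regulatory T-like cluster. On the positive side Plek, Tmcc1, Snrpf, Hist1h2ap, Cep85 and Cox5a lay between 1.07 and 1.19, Hist1h2ap being one of several near-identical histone genes. The ratios of Mt1 (2.20) and Spry2 (1.203) were positive with grafts that overlapped between the sorts. Of 1661 genes with at least 100 CPM in either, 47 had a log2 ratio of at least 1 and 50 of at most −1. Without antigen receptor and immunoglobulin segments, mitochondrial and ribosomal genes and unnamed gene models these were 11 and 48 of 1305. With all genes, under TMM scaling the split was 80 to 31, with a shift of −0.22.

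The recirculation list had a median log2 ratio of −3.31 in this contrast (percentile 0.0 among random lists), with Sell at −5.22 (1.14 against 78.6 CPM), Tcf7 at −3.31, Lef1 at −4.76 and Slamf6 at −2.33. Of 20 members in the limma test on graft sums, which was added after the data were seen, 17 were lower and 1 higher (camera adjusted p = 1.78e-11; adjusted p = 0.0339 with an estimated correlation). NK-type receptors had a median of 0.88 (above all 10000 random lists), with Klrd1 at 0.96, and 8 higher and 3 lower of 13 in the test (0.0164; adjusted p = 0.169 with an estimated correlation). Naive and central memory genes had a median of −3.37 (0.0), interferon-stimulated genes −1.08 (0.0), with Stat1 at −1.51, homing receptors −0.82 (0.0), subset transcription factors −1.34 (0.0) with Maf at −4.16, AP-1 genes −0.60 (0.01) and stress genes −0.57 (0.0). In the test these 6 lists had 8 of 9, 16 of 19, 10 of 14, 12 of 20, 12 of 18 and 9 of 18 members lower and 0, 1, 2, 4, 2 and 0 higher. Their camera adjusted p-values, at most 0.00459 at the preset correlation, were 0.0995, 0.31, 0.0771, 0.118, 0.317 and 0.169 with an estimated correlation. TGF-beta genes had 6 lower and 1 higher of 12 (0.0164; adjusted p = 0.115 with an estimated correlation). The resident memory list lay at −0.21 (24.54) and went both ways: in the test 9 members were higher, among them Itga1 (1.09 ± 0.16) and Cxcr6 (1.00 ± 0.23), and 7 lower, among them Itgae (−2.46 ± 0.21), of 27 (adjusted p = 0.756). Inhibitory receptors had 6 higher, with Pdcd1 at 0.88 ± 0.10, and 6 lower of 15 (0.793). Markers of regulatory T cells had 6 lower of 7 (0.000176; adjusted p = 0.0455 with an estimated correlation), and macrophage markers 6 lower of 8 (0.00377; adjusted p = 0.321 with an estimated correlation). The test called 2141 genes higher and 2202 lower of 10813, and 1312 and 3718 without TMM.

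Within the polyclonal library, CD4-gated cells were compared with CD8-gated cells, which come from the same library and have like depths per cell (medians of 2280.5 and 2251 counts), though the CD4 gate holds far fewer cells. Regulatory T markers, Il10 and Maf were higher in CD4 cells: Foxp3 stood at 189.8 against 32.7 CPM (log2 ratio 2.50), Il10 at 236 against 32.9 (2.81), Tnfrsf4, which encodes the costimulatory receptor OX40, at 997 against 179.8 (2.47), Maf at 279 against 52.8 (2.38) and Izumo1r at 1112 against 232 (2.26). Angptl2 (3.02), Timp2, Ly6a, Ass1 and Arl5a were also higher. Prf1, which encodes perforin, stood at 19.7 against 112 CPM (−2.45), Klrc2 at 32.0 against 342 (−3.38) and Itga1 at 8.63 against 85.9 (−3.17), and Spry2, Klrd1, Klrc1, St3gal6, Xcl1, Padi2, Bcl2 and Fcer1g were also lower, between −3.22 and −2.10. Most counts of the CD4 gate come from week 5 and most of the CD8 gate from week 1, so pooled ratios take in part of the change with time. The ratio of Cxcr6 was −1.30 pooled (377 against 932 CPM), −0.922 in week 1 cells and −0.281 in week 5 cells, and within grafts the limma test gave −0.69 ± 0.14. For Foxp3, Il10 and Itga1 that test gave 1.45 ± 0.34, 1.66 ± 0.21 and −2.38 ± 0.28, and Ass1 and Arl5a were not called. Of 1761 genes at 100 CPM, 62 had a log2 ratio of at least 1 and 29 of at most −1.

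The limma test on graft sums with a term for the graft, also added after the data were seen, called 155 genes higher and 300 lower in CD4 cells of 9292, against 248 and 174 without TMM, where the median of all genes moved from −0.185 to −0.075. The count was 298 without replicate 2 of week 5 and 299 without its replicate 3. Cytotoxicity genes had 10 lower and 1 higher of 13 (12 and 1 adjusted over the list alone), Gzma at −3.82 ± 0.38 and Prf1 at −2.15 ± 0.22 (camera adjusted p = 2.63e-09; adjusted p = 0.0566 with an estimated correlation). NK-type receptors had 5 lower and 1 higher of 15 (10 and 1 over the list alone; 1.13e-06; adjusted p = 0.0735 with an estimated correlation). Regulatory T markers had 7 higher of 8 (1.47e-21; adjusted p = 0.0384 with an estimated correlation), NK and ILC1 markers 3 lower of 6 (3.02e-05) and gamma delta T markers 3 lower of 5 (3.28e-05), both with an adjusted p = 0.0566 with an estimated correlation. The resident memory list had 5 higher and 7 lower of 28, with a negative median and a positive camera direction (0.907).

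For polyclonal cells, the share with a count of a resident memory gene was set beside that of a naive-like cluster of the same library (575 cells, 69.74% of them CD8-gated). Cxcr6 was counted in 81.9% of CD8-gated OT-I cells (80.9% to 82.9%), 67.5% of polyclonal CD8 cells and 40.1% of CD4 cells, and in 23.3% of the naive-like polyclonal cells. Thinned to 1200 counts per cell these shares were 70.25%, 54.4%, 27.3% and 14.1%, with median depths before thinning of 2115, 2456, 2482 and 2367 counts. Itgae was counted in 2.50% of OT-I and 16.3% of polyclonal CD8 cells, and in 4.87% of the naive-like polyclonal cells. Cd69 went the other way, with 51.1% of the naive-like cells against 42.1% of polyclonal CD8 cells (34.65% and 26.1% thinned). No background was set for the OT-I library. Pdcd1 was counted in 54.3% ± 4.92 of OT-I and 51.9% ± 2.16 of polyclonal CD8 cells at week 1 and in 65.4% ± 2.95 and 38.3% ± 4.82 at week 5 (SD, n = 3), so at full depth the sorts lay apart mainly at week 5. Thinned, the Pdcd1 shares were 49.5% ± 4.27 and 36.9% ± 1.21 at week 1 and 43.1% ± 1.64 and 22.7% ± 2.84 at week 5, and those of Itga1 16.5% ± 2.73 and 12.5% ± 1.49, then 9.23% ± 2.46 and 4.41% ± 1.45. At full depth the Itga1 share of OT-I cells was 21.2% ± 5.35 at week 1 and 20.6% ± 2.61 at week 5, so no order of the weeks is read from it. In thinned polyclonal CD8 cells Cxcr6 was counted in 69.0% ± 3.98 under the week 1 label and 31.3% ± 9.61 under the week 5 label (exact permutation p = 0.1, n = 3). In OT-I cells the Cxcr6 share was 75.7% ± 2.68 and 65.8% ± 6.85 after thinning but 79.4% ± 2.08 and 84.1% ± 3.41 at full depth, so no order is read from it. Ifng was counted in 10.8% ± 2.36 and 24.9% ± 2.44 of thinned OT-I cells.

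Within thinned polyclonal CD8 cells Cxcr6 was detected together with Itga1 more often than chance in 6 of 6 grafts (log2 odds ratio 1.08 ± 0.517, SD over grafts) and with Pdcd1 in 6 of 6 (0.809 ± 0.222). With Itgae the ratio was 0.608 ± 0.696, positive in 5 of 6. It was negative in all 6 grafts with Klf2 (−1.14 ± 0.328), Sell (−1.94 ± 0.774) and S1pr1 (−1.51 ± 1.29). With Cd69 it was 0.0881 ± 0.206. In thinned OT-I cells the ratio of Cxcr6 with Itga1 was 0.151 ± 0.37 and with Pdcd1 0.087 ± 0.17, within the spread between grafts, and with Klf2 it was −1.40 ± 0.759 over 5 grafts. At full depth in the same cells it was 0.251 ± 0.152 with Itga1, positive in 6 of 6 grafts. With Pdcd1 it was 0.292 ± 0.306 at full depth, positive in 5 of 6, so no lack of co-detection is read for OT-I cells.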

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

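The tests of thinned cells for resident memory and AP-1 genes were chosen after the results were seen. A test of the interaction marked 163 genes whose change between time labels differed between OT-I and polyclonal CD8 cells, and the 25 genes named by the rule are given first, as log2 differences with 3 grafts per group. Larger rises or smaller falls in OT-I cells were found for Cx3cr1 (2.67), Igfbp7 (2.19), Ccl5 (1.71), Nr4a2 (1.69), Adgrg1 (1.62), Ramp1 (1.52), Cd200r4 (1.45), Klf6 (1.40), Cd244a (1.36), Emp3 (1.33), Rbpj (1.23), Sik1 (1.165), Slamf6 (1.08), Itga1 (0.83) and Rgs2 (0.79). The opposite sign was found for Satb1 (−2.36), Ikzf2 (−1.29), Adk (−1.21), Txk (−1.19), Ctsz (−1.12), Retreg1 (−1.11), Slc29a1 (−1.11), Itgb7 (−1.05), Crtam (−1.05) and Ssbp2 (−0.95). Ramp1 had only 0.148 and 3.09 CPM in OT-I cells, so its difference rests on few counts. Slamf6, at 2.45 CPM in OT-I cells labelled week 1, turned to −0.16 at a pseudocount of 10 CPM and to −1.82 with means of the deposited values, as Ramp1 did (−0.49). Of 100 splits that exchange time labels within the sorts, 4 gave as many genes, the real one included, and the highest gave 502. The 3 splits above 163 (223, 350 and 502 genes) exchange the labels of all 6 polyclonal sums and of 2 OT-I sums. Such an exchange makes the term add the time changes of the sorts in place of subtracting them. Every split but the real one also mixes the weeks in at least 1 sort. Time changes then enter the spread between sums and lower the calls (median 0). The splits thus give no chance level for an interaction.

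Of 29 resident memory genes 13 were lower, Itga1, Itgae and Cxcr6 among them, and 2 higher in polyclonal CD8 cells labelled week 5 (camera adjusted p = 0.000117; adjusted p = 0.338 with an estimated correlation). In cells thinned to 1200 counts the list's median was −0.431. Thinning hardly changes the CPM of summed counts, and the gates were set before thinning. This test therefore cannot decide whether depth plays a part. A wrong time label on single hash tags is argued against: 0 of 12 graft sums correlated better with grafts of the other label. An exchange of all time labels in both sorts cannot be told apart from the labels as given, because it would leave the correlation between the changes of the sorts (r = 0.52) as it is. A change of the cells in the graft with time and a change in which cells enter it both stay open and were not tested.

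Of 18 AP-1 genes 4, among them Nr4a2, Junb and Jund, had a higher change in OT-I than in polyclonal CD8 cells (camera adjusted p = 9.3e-09; adjusted p = 0.0558 with an estimated correlation). The heat-shock members of the stress list did not move with the AP-1 list: their median difference was −0.021 over 8 genes, with 0 called, against 0.64 for the AP-1 list. That argues against stress of dissociation as far as it acts on heat-shock genes, while 8 genes stand on both the AP-1 and the stress list. In thinned cells the median was 0.50, but thinning hardly changes the CPM of summed counts, so this cannot decide whether depth plays a part. A difference in receptor signalling stays open and was not tested.

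With 3 against 3 grafts there are 10 splits, too few for a share under 0.05. The real split gave 1053 genes in OT-I cells against at most 1 in the others, 2115 against 4 in polyclonal CD8 cells and 45 against 0 in CD4 cells, and in each 1 of 10 splits, the real one, reached its count. Between the sorts 1 of 100 splits reached 4343 genes, the next highest giving 1, and between CD4 and CD8 cells 1 of 32 reached 455, the next highest giving 1.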

How the results depend on the processing

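The edgeR test was the one planned for the time comparisons and the interaction, and limma-trend replaced it after the files were seen. The planned test called 1113 genes in OT-I, 2317 in polyclonal CD8 and 101 in CD4 cells, and 213 in the interaction. Tests without TMM, with other pseudocounts, in thinned cells and with other cell filters or gates were chosen after the files were seen. So were those without proliferating or other cells, with means over cells, of cells of 1 week only and with gene sets left out. Between sorts or between CD4 and CD8 cells, so were edgeR and the fits with grafts left out. The OT-I and polyclonal sums come from the same 6 grafts, but which tags share a graft is not stated, so the fits between the sorts treat the sums as independent. Pairing by order of tag numbers was tried as a replicate block after the results were seen. Deviations of same-numbered sums correlated between the sorts by 0.00859 to 0.167, over 0.1 in 2 of 6 pairs, and 5 of 6 OT-I sums correlated best with their own number, a hint from the data and not the design. With this block the interaction gave 515 genes (163 without) and the test between the sorts 4462 (4343 without). Within a sort no paired analysis was possible because week 1 and week 5 grafts are different animals. Alternatives without doublets were not run, since 0 were called. The CD4 comparison rests on 56 to 319 cells per graft. Except where fewer grafts, cells or counts lower the power by construction, the cause was not tested for any value here.

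Counts of genes in OT-I cells (1053) were 695 with DESeq2, 468 in thinned cells, 3882 with means of the deposited values, and 603 to 991 with 1 graft left out. In polyclonal CD8 cells (2115) they were 927 thinned and 1274 to 2371. In CD4 cells (45) they were 101 with edgeR, 14 at 1000 counts per cell, 4 thinned, 25 with clusters, 1947 with means and 11 to 37. The interaction (163) gave 100 thinned, 622 with means and 82 to 243. CD4 against CD8 (455) gave 1025 with edgeR, 691 with DESeq2, 757 without the count filter, 255 thinned, 1096 with clusters, 720 with means, 244 without mitochondrial, ribosomal and Gm genes and 298 to 501. Ratios past 1 numbered 190 and 56 at 50 and 200 CPM between the sorts, and 159 and 46 between CD4 and CD8 cells.

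With means of the deposited values the direction turned for Ccl3 in CD4 cells (0.94), for Ramp1 (−0.49) and Slamf6 (−1.82) in the interaction, and there for the camera direction, but not the sign of the median, of circulating effector genes (median 0.359), erythroid markers (0.033), kidney tubule markers (0.021) and subset transcription factors (0.146). Slamf6 also turned at a pseudocount of 10 CPM (−0.16), and the ratio of Dapl1 between CD4 and CD8 cells in week 1 cells (1.03). With clusters in place of gates, the median and camera direction turned for proliferation (−0.259) in the interaction and for B (0.982) and plasma cell markers (0.199) between CD4 and CD8 cells. The direction alone turned for regulatory T markers (0.959) in the interaction and for recirculation between CD4 and CD8 cells (−0.688, and −0.341 with edgeR), whose median was negative before (−0.169, camera adjusted p = 0.907).

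The share with Cxcr6 was 70.25% in thinned OT-I cells, 83.54% at 1000 counts, 54.39% in thinned polyclonal CD8 and 27.31% in thinned CD4 cells. Named OT-I cells made up 7.946% at resolution 1.2, 8.538% with 10 components and 7.837% without proliferation genes. Named polyclonal cells made up 51.12% and 49.15% at resolutions 0.4 and 1.2, 44.91% and 50.05% with 10 and 30 components and 45.57% without proliferation genes. At 1000 counts 88.78% of OT-I and 94.08% of polyclonal cells were kept. Of values for named genes under the alternatives, 677 kept direction and call in OT-I cells and 58 lost the call, against 870 and 50 in polyclonal CD8, 304 and 148 in CD4 cells and 629 and 118 in the interaction. Of values for lists, 20 lost the call in OT-I cells, 4 in polyclonal CD8 cells, 11 in CD4 cells and 51, over 7 lists, in the interaction.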

Other observations

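The test of ribosomal families matched by sequence was chosen after the result was seen. In polyclonal CD8 cells labelled week 5, Cxcr5, a homing receptor for B cell follicles, was higher by 2.39 ± 0.38 (log2, SE, n = 3 grafts, limma adjusted p = 0.00023). The CD8 gate also held cells of clusters with CD4 T markers, and which cells carry Cxcr5 was not tested. Csf1, a macrophage growth factor gene, was lower by 2.09 ± 0.23. In CD4 cells Il21, a helper cytokine gene, exceeded CD8 cells by 2.81 ± 0.37 (adjusted p = 0.00138).

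The changes between time labels were shared in part by the sorts. Of 9522 genes tested in both OT-I and polyclonal CD8 cells, 576 were called in both and 554 in the same direction. Of these 350 were higher in both, among them Ly6c2 and Slamf6, and 204 were lower in both, among them Itga1 and Itgae. If calls in the sorts were independent, 69.7 higher and 38.3 lower in both would be expected. The sums of both sorts come from the same grafts, so independence cannot be assumed. No excess over chance is therefore read from these expected values.

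The ribosomal protein gene Rpl29 had 5.44 CPM in OT-I and 1147 CPM in polyclonal CD8 cells (log2 ratio −7.48), while Rpl14-ps1 had a ratio of 2.26 against −0.94 for its parent Rpl14. Reads shared between a gene and its pseudogenes were weighed with families matched by symbol, as planned. There 2 of 51 families switched, and the median size of their family sums was 1.01. By the rule set beforehand, a median over 1 goes against shared reads. The 2 sums lay far apart, at −1.699 for Rpl29 and 0.32 for Rpl14. Symbols also matched only 149 of the 1137 pseudogenes of any kind, so this test decides little. With families matched by sequence, 2 of 76 switched and the median was 0.199, with Rpl29 family sums of 1142 and 1205 CPM, as shared reads would give. A strain variant in 1 linked segment cannot be told apart, since both parent genes lie on 1 chromosome (Rpl29 at 9:106429454-106431568, Rpl14 at 9:120571444-120574654). Reads assigned differently when the libraries were processed cannot be told apart either: 12 of 12 graft sums lay on their library's side, and sort and library coincide.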
